A study of Danio rerio with 10 samples.

How the data were processed

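The series covers kidney marrow of adult zebrafish, the main blood-forming tissue of this fish, in wild-type animals and in animals mutant for gata2a, a gene for a haematopoietic transcription factor. The labels list 10 samples: 1 scRNA-seq library per genotype at 12 months post-fertilisation, 1 per genotype at 5 months, and 3 scATAC-seq libraries per genotype at 5 months. Single-cell ATAC-seq cuts accessible DNA of single nuclei with a transposase, and each sequenced fragment carries a cell barcode and has an insertion at both ends.

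Per the submitters' processing notes, Cell Ranger, Cell Ranger ATAC, MACS2 and MACS3 were used with the zebrafish build GRCz11. Tool versions are not given in the sources used here. The deposited scATAC-seq values are counts: each line of a single file for all libraries holds 1 unique fragment, its position on GRCz11, its barcode and the count of read pairs behind it. The file holds fragments of chromosomes 1 to 25. The barcodes end in the suffixes 1 to 6, and no label used here ties a suffix to a sample, so the suffixes are called libraries 1 to 6 and none was given a genotype. The file was therefore treated as 1 pooled sample: no test between genotypes was made and no p-value is given, and values are given per library or as a range and median. The deposited list of cell barcodes of the 12-month scRNA-seq libraries names the library of each barcode and holds no expression value. Expression values of the scRNA-seq libraries were not analysed here.

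A barcode with at least 1000 fragments was taken as a cell. Filtering on enrichment at transcription start sites, gene lists, cell type markers, motif shares and the gata2a locus had been planned before the data were examined. All of them need gene positions or the sequence of GRCz11, and the annotation used here is of another build (GRCz12tu), so these were not analysed here. Clusters stay numbered, and regions are given by position, without gene names. The planned rule for named genes was replaced, after the data had been seen, by the rule that the regions named for a cluster are those with the highest fold among its regions with at least 100 insertions in it.

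Cells were described by the presence of fragments in 5 kb bins seen in at least 1% of cells, which left 38406 bins. The matrix was weighted by term frequency and inverse document frequency and reduced to 30 components by singular value decomposition. The components with a correlation over 0.5 with the logarithm of the fragment number were left out, and 29 were used. Doublets were sought with 17784 simulated pairs of cells of the same library, and the cells with the highest share of simulated pairs among their 30 nearest neighbours were removed, at 0.8% per 1000 cells of a library. This removed 2337 of 35570 cells. Of the simulated doublets, between 13.4% and 44.9% per library reached the score at which cells were removed, so the removal was partial. The Leiden algorithm at resolution 0.6 with seed 0 gave the clusters, numbered by size. The planned removal of bins near listed genes was not possible without gene positions.

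The genome was divided into 500 bp tiles. A tile was called open when the cells of all libraries had at least 300 insertions in it, 10 times the median tile, and adjacent open tiles were merged into regions. To keep the regions of a cluster apart from the data that defined it, cells were clustered again on odd-numbered chromosomes alone and regions were measured on even-numbered chromosomes. The odd-chromosome clusters were matched to the main clusters where the Jaccard index of their cells was at least 0.5. To compare cluster shares between settings, a looser rule was used. A cluster then had a counterpart where the index was at least 0.3 and each was the best match of the other. A region was called higher in a cluster when its insertion CPM (counts scaled to all insertions of the cells compared) was at least 2-fold that of all other cells, both pooled and in every library with at least 100 cells of the cluster. Folds have exact conditional binomial intervals and shares exact Clopper-Pearson intervals, both at 95%. Where a ratio of shares was taken, 3 counts stand for a count of 0. Intervals cover counting error only. Both ends of a fragment count as separate insertions and can fall in the same region, so the intervals of folds are too narrow even for counting error.

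An open tile was called nearly empty in a library when at most 10% of the expected insertions were found, with at least 20 expected from the rates of the same clusters in the other libraries. Both calling steps were tested on simulated data. With 16953 regions and 200 of them raised in 1 of 12 clusters at a time, between 43.0% and 97.0% of the regions raised 3-fold and between 94.0% and 100.0% of those raised 6-fold were recovered. At most 45 unchanged regions were called, in cluster 13. Among 59928 tiles, 200 pairs of tile and library at a time were lowered to 5%, 20% or 50% of their expected insertions. Of these, 94.5%, 2% and 0% were called, so that tiles lowered to 20% or more are mostly missed, and 0 other pairs were called. In both simulations counts varied by counting error alone, with the same rates in every library. Insertions were drawn independently, though both ends of a fragment can fall in the same region or tile. The shares recovered and the calls of unchanged regions or tiles are therefore no error rates for the real data.

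The alternatives fixed before the data were examined were a minimum of 3000 fragments per cell for the number of cells and the clusters, no removal of doublets for the clusters, a region fold of 4 for the regions of clusters, and each library left out in turn for the clusters and their regions. For the regions of clusters, the minimum of 3000 fragments and the run without doublet removal were added later, and for the correlations between libraries and the chromosome 4 block all alternatives were. Also added afterwards were other clustering resolutions, seeds and scalings, clustering on odd or even chromosomes alone, scaling to insertions in open regions, cells with at least 20% of insertions in open regions, and other thresholds for open and nearly empty tiles. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.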

Results

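Chromatin accessibility was measured in single nuclei of zebrafish kidney marrow at 5 months post-fertilisation, with 3 wild-type and 3 gata2a-mutant libraries in the labels. The deposited fragments carried the barcode suffixes 1 to 6, called libraries 1 to 6 here, and the genotype of each was left open. The labels also list 4 scRNA-seq samples, 1 per genotype at 12 and at 5 months. Those at 12 months were represented by a list of 178 cell barcodes, of which 106 were assigned to the wild-type and 72 to the mutant library, and those at 5 months were not analysed here. Differences between genotypes, which the design was made to measure, were not analysed here. There were no mapped replicates, so differences between libraries are given as values without a test.

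The libraries differed in depth. The file held 149714205 unique fragments from 196925482 read pairs. Libraries 3 and 4 had 41073726 and 41725060 fragments, and libraries 1, 2, 5 and 6 had 17774264, 15325691, 18060489 and 15754975. Each fragment was seen in 1.18 to 1.46 read pairs, with a median of 1.35 over the 6 libraries, so most fragments rested on a single read pair. Between 70.1% and 86.4% of fragments were seen once.

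Cells with at least 1000 fragments numbered 4390, 3502, 10706, 11430, 2705 and 2837 in libraries 1 to 6, 35570 in all. They held 59.13% of all fragments, from 34.4% in library 5 to 75.9% in library 2. The median cell had 1601 fragments in library 3 and 2212 in library 2, the lowest and highest of the 6. With a minimum of 3000 fragments, 7889 cells were left.

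Fragment lengths had the pattern left by nucleosomes in all 6 libraries. Fragments under 150 bp, about the length of DNA wrapped around a nucleosome, made up 48.7% in library 2 and 68.2% in library 6, the lowest and highest shares. Those of at least 150 and under 300 bp made up 26.6% in library 6 and 41.1% in library 5, with the most frequent length between 193 and 203 bp. Fragments of at least 300 bp ranged from 4.29% in library 3 to 10.95% in library 1.

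**Figure D1:**
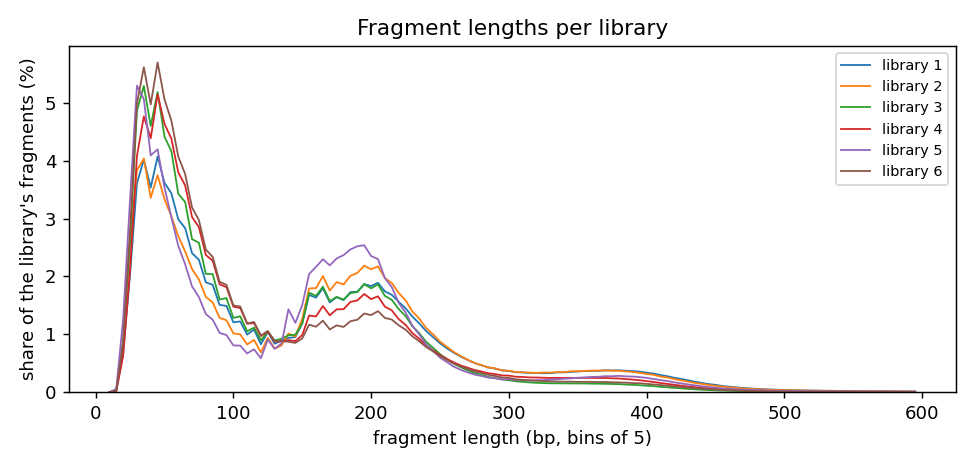
Share of each library's fragments (%, y axis) by fragment length (bp, x axis, bins of 5 bp) for libraries 1 to 6. Each line is 1 library, with a peak of short fragments and a further peak whose most frequent length lies between 193 and 203 bp.

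Open chromatin covered a small part of the genome. Pooled cells gave 37107 open regions, which spanned 29.96 Mb or 2.23% of the tiles and held 43.8% of the insertions. The median region was 500 bp long and the longest 10500 bp. Of the regions, 35154 (94.7%) had at least 10 insertions in every library and 108 (0.291%) had none in at least 1 library. By the rule each region has at least 300 insertions over all libraries, so these shares say little on agreement between libraries. The share of a library's insertions in open regions was 33.7% in library 5, 38.0% in library 3, 40.9% in library 6, 44.2% in library 1, 47.6% in library 4 and 51.4% in library 2. Across regions, the log2 insertion CPM (counts scaled to the total of the library) of 2 libraries correlated with Pearson's r between 0.845 and 0.962. These correlations are across regions, which are not independent replicates.

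A 40 Mb block of chromosome 4, from 31000001 to 71000000, had few insertions. It was picked as the megabases of this chromosome with a low density against the genome mean, so its low pooled density follows from the pick. All 40 megabases between its ends fell below the limit used. The long arm of this chromosome is known as rich in repeats and heterochromatin. The block had 7.88 insertions per kb, against 139.2 in the rest of chromosome 4 and 131.6 over the genome. It held 34 open regions, against 1230 in the rest of the chromosome. Relative to the genome mean, its density was 0.0471 in library 2, the lowest, and 0.0762 in library 5, the highest. Outside open tiles the density relative to the genome lay between 0.0769 in cluster 14 and 0.1085 in cluster 8. The other 24 chromosomes, each taken as a whole, had 115.7 to 150.6 insertions per kb and 22 to 35.1 open regions per Mb. Shorter stretches of them were not examined. Reads that map to several places are a limit here, since their treatment is not given in the sources used here.

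**Figure D2:**
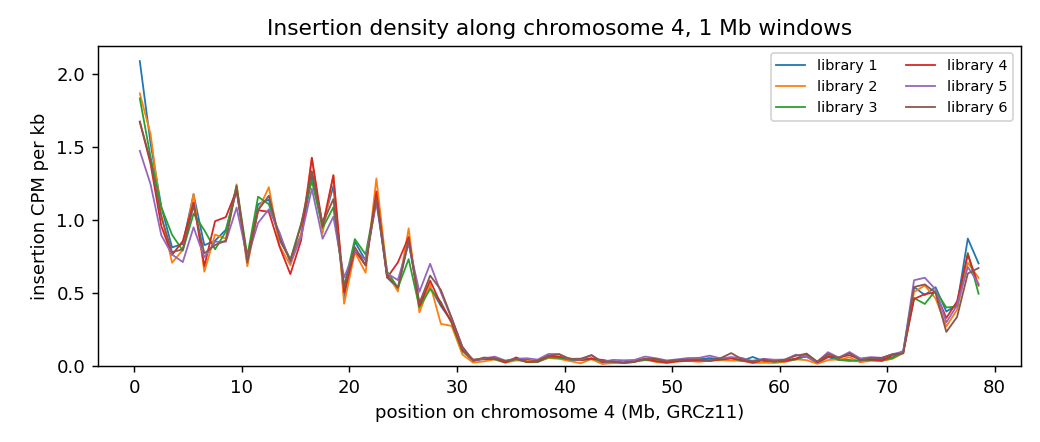
Insertion CPM per kb (y axis) in 1 Mb windows along chromosome 4 (Mb, GRCz11, x axis), 1 line for each of the 6 libraries. From 31 to 71 Mb every library lies near 0, with a density of 0.0471 to 0.0762 of its genome mean. This stretch was picked for its low density in pooled cells.

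The 33233 cells left after removal of doublets fell into 14 clusters of 530 to 7489 cells. In 5 clusters the highest share of a library was at least 10 times the lowest. Cluster 7 made up 19.0% of the cells of library 1 (95% interval 17.9 to 20.2) and 8.71% of library 3 (8.16 to 9.29). In library 2 its share was 1.97% (1.53 to 2.49), in library 6 it was 0.361% (10 of 2773 cells) and in library 5 it was 0.076% (2 of 2646 cells). Library 4 had 0 of 10385 cells in cluster 7, with an upper 95% limit of 0.036%.

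Cluster 2 held 27.9% of library 2 and 22.9% of library 4, against 1.32% of library 3 and 1.06% of library 5. Cluster 3 ran the other way in these libraries, with 29.0% of library 3 and 21.2% of library 5 and 2.26% and 2.55% of libraries 2 and 4. Libraries 3 and 5 were also those whose median cell had the lowest share of insertions in open regions, 40.8% and 41.7% against 53.6% to 59.7% in the other libraries. Cluster 3 had no counterpart when cells were clustered without library 3, with at least 3000 fragments per cell or at resolution 1.0. Of all cells it held 12.5%, and 21.9% on odd chromosomes, 22.9% on even chromosomes and 24.2% with scaled components. Cluster 6 had its highest share in library 4, at 14.4% (13.7 to 15.1), and its lowest in library 3, at 1.32% (1.101 to 1.56). Cluster 10 held 17.3% of library 2, 12.2% of library 6 and 5.69% of library 1, with 1 cell of library 3, 13 of library 4 and 0 of library 5, with an upper 95% limit of 0.139%. Its median cell had 3711 fragments, against 1469 in cluster 1. Cluster 10 had no counterpart with odd or even chromosomes alone, seed 1, resolution 0.3, scaled components or without library 3. Where it was matched, its share of all cells moved from 3.56% to 13.7% without library 4, 11.5% without doublet removal, 17.2% with at least 3000 fragments, 2.08% without library 1 and 1.96% without library 2. On odd chromosomes its best match, with a Jaccard index of 0.141, was the cluster that matched cluster 1.

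The shares of the other clusters spanned less than 10-fold between libraries. Cluster 1 ranged from 13.3% in library 4 to 34.8% in library 6. Cluster 4 ranged from 2.27% in library 6 to 22.6% in library 5. It had no counterpart with scaled components, on odd or even chromosomes alone or with at least 3000 fragments per cell. Cluster 5 lay between 3.90% and 9.33%, cluster 9 between 1.83% and 6.58%, and cluster 13 between 0.613% and 2.01%. The share of cluster 9 among all cells, 4.45%, was 2.16% without library 3, 2.25% without library 5, 2.77% without library 4, 2.17% with seed 1 and 2.16% to 2.28% at resolutions 0.3 and 1.0, with scaled components and without doublet removal. Cluster 8 had no counterpart at resolution 0.3, with seed 1, with scaled components, without doublet removal or without library 1. Clusters 3 and 8 had little signal in open regions: the median cell of cluster 8 had 10.8% of its insertions there, with 5444 fragments, and that of cluster 3 had 25%, with 1588 fragments. Within cluster 3 this median was 28.1% in library 3 and 25.9% in library 5, and 10.6%, 12.1%, 14.2% and 6.61% in libraries 1, 2, 4 and 6. In the other 12 clusters the median was 37.1% to 61.8%.

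**Figure D3:**
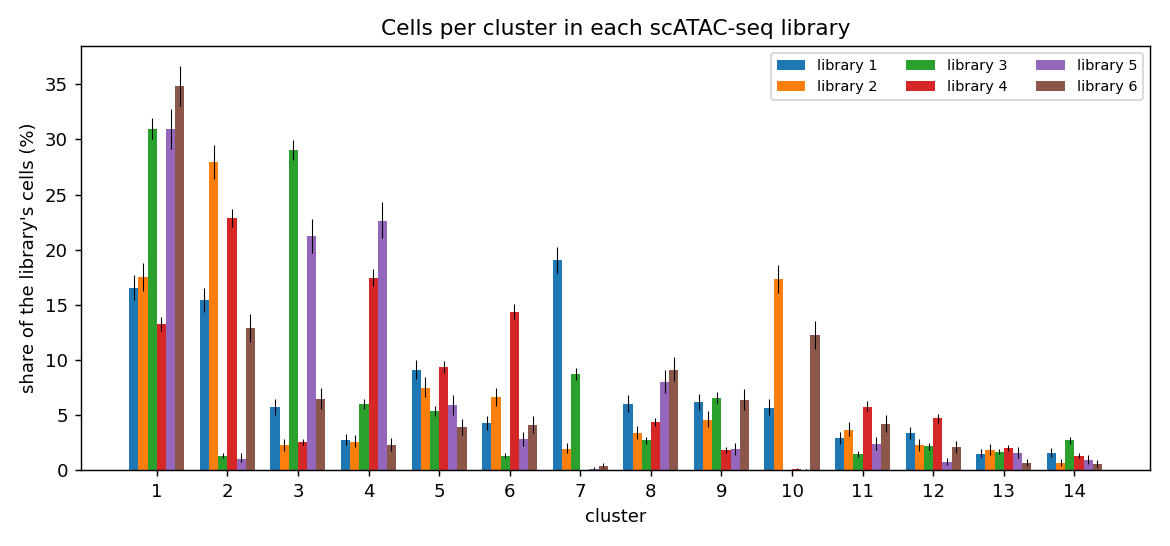
Share of each library's cells (%, y axis) in clusters 1 to 14 (x axis), 1 bar per library with its exact 95% binomial interval, which covers counting error only. Cluster 7 reaches 19.0% in library 1 and 8.71% in library 3 and has 0 cells in library 4.

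Cluster-specific accessibility was measured on 16953 open regions of even-numbered chromosomes, with cells clustered on odd-numbered ones. Of these regions, 9756 (57.5%) were at least 2-fold higher in at least 1 of 12 clusters, 6949 of them in a single cluster. Cluster 2 had 2414 such regions, cluster 13 had 1858, cluster 6 had 1507, cluster 14 had 1422, cluster 5 had 1214, cluster 7 had 1155 and cluster 11 had 1034. Clusters 1, 12 and 9 had 846, 772 and 622. Cluster 8 had 30. Cluster 3 had 0, but the odd-chromosome cluster matched to it (Jaccard index 0.538) held 7281 cells and was also the best match of cluster 4 (0.252), so this value is for a mix of both. Clusters 4 and 10 had no match of their own. The odd-chromosome cluster matched to cluster 1 (Jaccard index 0.812) held 8383 cells and was also the best match of cluster 10 (0.141). Values for cluster 1 are therefore for a mix of both. The odd-chromosome cluster matched to cluster 2 held 5602 cells, against 4493 in cluster 2 itself. With insertions scaled to those in open regions, the count fell to 143 in cluster 1, 1526 in cluster 2 and 1029 in cluster 13 and rose to 161 in cluster 8, as this scaling shifted log2 folds by -0.43, -0.55, -0.45 and 1.899 in these clusters. Without library 4 the count was 3839 in cluster 13 and 2295 in cluster 14, without library 5 it was 1430 in cluster 1, and without library 3 it was 49 in cluster 8. Leaving out a measured library loosens the rule, since a region must then be higher in fewer libraries. Clusters 1, 2, 3, 5 and 8 were measured in 6 libraries and cluster 9 in 5. Clusters 6 and 11 were measured in 4, cluster 12 in 3 and clusters 7, 13 and 14 in 2, so the counts rest on unlike rules.

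The leading regions of clusters were picked for their folds in the same data. Their folds therefore tend to be too high, and the counting intervals do not allow for the pick. The region with the highest fold in cluster 14 lay on chromosome 18 from 9132501 to 9133000. It had an insertion CPM of 77.0 in the cluster and 0.72 in other cells, a fold of 106.3 (95% counting interval 83.1 to 136.4), with folds of 75.3 and 125.5 in the 2 libraries with enough cells. With cells clustered on even chromosomes alone, cluster 14 had no counterpart. Its best match there, with a Jaccard index of 0.242, was also the best match of cluster 9 (0.706). In cluster 7 the region on chromosome 8 from 54177501 to 54178000 had a fold of 59.3 (45.8 to 77.6), with 28.7 and 54.8 within the 2 libraries that could be measured. The pooled fold compares with cells of all 6 libraries. In cluster 13 the region on chromosome 10 from 29688001 to 29688500 had a fold of 55.2 (43.8 to 69.6). In cluster 11 the region on chromosome 4 from 17586001 to 17586500 had a fold of 52.6 (41.1 to 67.5), which ranged from 18.7 to 379 over 4 libraries.

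The leading region of cluster 12, on chromosome 8 from 24829001 to 24829500, had a fold of 48.6 (38.3 to 61.6). For cluster 9 it lay on chromosome 10 from 35656001 to 35656500, with a fold of 45.0 (35.4 to 57.6). For cluster 6 it lay on chromosome 22 from 11556501 to 11557000, with a fold of 44.7 (35.4 to 56.9). For cluster 5 it lay on chromosome 8 from 5204501 to 5205000, with a fold of 42.7 (35.0 to 52.4) that ranged from 9.66 to 348 over 6 libraries. A lower fold was found for the leading region of cluster 2, on chromosome 22 from 24216501 to 24217000, at 22.2 (17.1 to 29.3). Cluster 1, here a mix with cluster 10, led with a region on chromosome 2 from 52315001 to 52315500, at 10.96 (9.79 to 12.3). In cluster 8 the highest fold was 4.05 (3.32 to 4.92), on chromosome 24 from 16279501 to 16280000. Scaled to insertions in open regions, this fold was 15.1, that of the leading region of cluster 2 was 15.2 and that of cluster 1 was 8.13, the lowest of the 11 clusters.

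**Figure D4:**
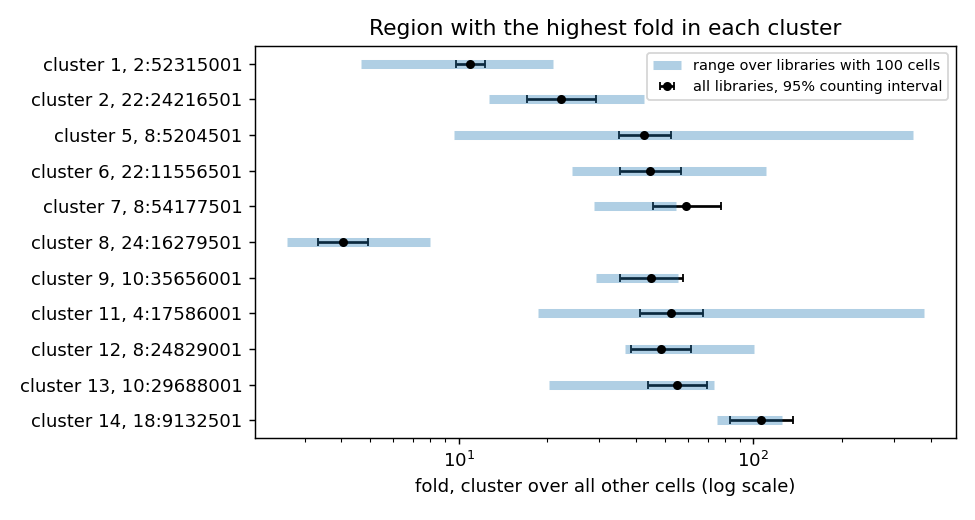
Fold of insertion CPM in a cluster over all other cells (x axis, log scale) for the region with the highest fold in each of 11 clusters (y axis, GRCz11 start). Points are pooled over libraries with 95% counting intervals, pale bars give the range over libraries with at least 100 cells of the cluster, and folds run from 4.05 in cluster 8 to 106.3 in cluster 14 (scaled to insertions in open regions, cluster 1 is the lowest, at 8.13). Cluster 1 is here a mix with cluster 10. The regions were picked for these folds, and the intervals do not allow for that.

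The 100 kb windows with the most regions of a cluster were picked for their counts, and grouping along the chromosome was not tested. In cluster 1, here a mix with cluster 10, 11 of the 17 open regions of the window on chromosome 22 from 16500001 to 16600000 were at least 2-fold higher. In cluster 13 this held for 11 of 16 in the window on chromosome 22 from 5300001 to 5400000, and in cluster 6 for 8 of 10 on chromosome 24 from 38200001 to 38300000. In cluster 12 it held for 7 of 9 on chromosome 18 from 23200001 to 23300000. The windows with the most regions of clusters 8 and 9 held 4 each, of 8 open regions on chromosome 2 from 19400001 to 19500000 and of 11 on chromosome 2 from 24500001 to 24600000. Across the 16953 regions, cluster 8 and the odd-chromosome cluster matched to cluster 3, which mixes clusters 3 and 4, had the most similar profiles (Pearson's r of log2 values 0.941) and clusters 2 and 14 the least similar (0.469).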

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

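The tests of the barcode list were chosen only after the list had been seen. The list of cell barcodes of the 12-month scRNA-seq libraries, which enters no comparison above, gave a signal of its own. Of its 178 barcodes of 16 bases, 134 (75.3%, 95% interval 68.3 to 81.4) ended in 1 of 2 sequences of 8 bases. The ending ACATGGGA was carried by 74 barcodes and ATTTGCCC by 60. Either ending was found in 76.4% of the 106 wild-type and 73.6% of the 72 mutant barcodes, and 10 of the 168 distinct barcodes were listed for both libraries.

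Chance in drawing that many barcodes was argued against: in 10000 random draws of 178 scATAC-seq cell barcodes, which come from another pool of sequences, the commonest ending was carried by at most 5 barcodes. For ACATGGGA, a candidate explanation is that the end of the template-switch oligo of the 3' kit was read as part of the barcode: the ending holds a 7-base word of that oligo, taken from background knowledge of the kit, which is a single match of sequence. Of all 178 listed barcodes, 80.3% had C at position 8, just before the ending. Whether the oligo has C at that place was not checked, so the match covers the 7-base word alone. Of the 16 other distinct endings, 5 (31.25%, 95% interval 11.02 to 58.7) had a barcode with such a word, 12 of 44 barcodes, against 1.73% of scATAC-seq cell barcodes. For ATTTGCCC this explanation was argued against, as the ending holds 0 such words, and the origin of that ending stays open. Both endings occurred in both genotypes, and no biological explanation was tested.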

How the results depend on the processing

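Settings other than 3000 fragments, no doublet removal, fold 4 and leaving out libraries were chosen only after the data were seen. For the regions of clusters, 3000 fragments and no doublet removal were also chosen then, and for the correlations between libraries and the chromosome 4 block every setting was. No paired analysis was possible because no label ties a barcode suffix to a sample or replicate number. The transcription start site minimum, gene windows and gene lists, the gata2a locus and all fits between genotypes were not run, for want of gene positions on GRCz11 or of a sample for each suffix. With at least 3000 fragments, libraries 1 to 6 kept 1154, 1120, 1473, 2805, 557 and 780 cells, and cluster 7 held 32.5% of library 1. The number of clusters was 11 to 18 under all settings (14 to 16 without 1 library), but of the 14 clusters only 8 had a match with at least 3000 fragments, 11 at resolution 0.3 and 12 without library 3. With at least 3000 fragments clusters 3, 4, 6, 11, 12 and 13 had none. Clusters whose library shares span 10-fold numbered 3 with scaled components, 3 on odd and 3 on even chromosomes, and 4 to 7 without 1 library. At resolution 1.0 cluster 7 held 20.4% of library 1, and without 1 library 18.7% to 19.1%. It had 0 cells of library 4 under every setting run. Pooled cluster shares left their counting interval under other settings in 120 cases and stayed within it in 52; the cause was not tested. With at least 3000 fragments the pooled share of cluster 1 fell from 22.5% to 10.04% and that of cluster 14 from 1.595% to 0.579%, and cluster 8 rose from 4.67% to 17.5% and cluster 7 from 5.23% to 13.4%. Without library 3 cluster 2 went from 13.5% to 21.7% and cluster 8 to 9.73%, without library 4 cluster 4 went from 9.83% to 5.61% and cluster 6 from 6.66% to 3.51%, without library 5 cluster 4 went to 6.44%, and without library 1 cluster 7 went to 3.26%. With fold 4, 3902 regions were higher in at least 1 cluster, by construction fewer. Without 1 library 10016 to 11426 were, where the rule asks for fewer libraries. With the odd-chromosome clusters kept as they were, their cells with at least 3000 fragments gave 1394, 3401, 2333 and 16 regions in clusters 1, 5, 6 and 3 (cluster 1 a mix with cluster 10 and cluster 3 a mix with cluster 4), and clusters 9, 11, 12, 13 and 14 had no library with enough such cells to be measured. Cells with at least 20% of insertions in open regions gave 315 in cluster 1. Open regions numbered 69201 at 5 and 22441 at 20 times the median tile. Nearly empty tiles numbered 875 at 20% of the expected insertions. Counted once per distinct sequence, 75.6% of the listed barcodes had either ending. The lowest correlation between libraries was 0.912 without library 4. Depth limits the calls of regions: on simulated data, the median share of regions raised 3-fold that were recovered over 12 clusters was 74% at the real depth and 39.5% at 25% of it, with the same cells and rules. Unchanged regions called in a cluster numbered at most 45 at the real depth and at most 391 at 25% of it.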

Other observations

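The tests of shallow barcodes and of a cell state confined to a single cluster were chosen only after their values had been seen, and the patterns in this part were noticed in the data before any test. Single libraries lacked signal at open chromatin that the same clusters had in other libraries. Of 59928 open tiles, 452 were nearly empty in at least 1 library, with 151, 89, 70, 104, 122 and 106 tiles in libraries 1 to 6. Runs of tiles without an insertion in a library were sought apart from this, among all tiles, open or not. At least 20 insertions had to be expected from all cells of the other libraries, not matched by cluster. On chromosome 22 from 34659501 to 34668500, library 3 had 0 insertions and libraries 1, 2, 4, 5 and 6 had 1184, 477, 1668, 22 and 251. On chromosome 23 from 43612501 to 43613500, library 4 had 0 insertions and libraries 1, 2, 3, 5 and 6 had 993, 120, 1823, 650 and 10. On chromosome 15 from 40165501 to 40177000, library 1 had 0 insertions, library 2 had 8 and library 4 had 1876. Such runs reached 184500 bp in library 4, and they need not be open chromatin. All 15 pairs of libraries shared more nearly empty tiles than independent draws give, from 3 in libraries 3 and 6, against 0.119, to 55 in libraries 1 and 2, against 0.217. Libraries 1 and 6 shared 38, libraries 3 and 5 shared 26 and libraries 2 and 6 shared 21.

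A sequence variant or deletion carried by the fish of a library may account for such tiles, and so may a cell state that differs in it. Tiles called in odd-numbered clusters alone were measured in even-numbered ones: 424 of 523 pairs of tile and library (81.1%, 95% interval 75.1 to 85.6 with chromosomes redrawn) were low there too, against 1.05% of all pairs, and insertions there were 9.59% of those expected. A cell state confined to a single cluster was thus argued against as the cause of the whole pattern, as it leaves other clusters unchanged. A variant and a cell state more or less common in a library cannot be told apart: the share is above the 50% set beforehand for such a state, but the 80% set both for a variant and against a cell state lies inside the interval, and a state can span clusters. Reads shared between near-identical sequences were not examined, and genotype, which the design names, stays open and untested.

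Cluster 7 was nearly missing from libraries 4, 5 and 6. At its 1155 regions on even chromosomes, cells of cluster 7 had an insertion CPM of 25688 in library 1, and the cells outside it had 5958 in library 1, 5213 in library 4, 3459 in library 5 and 4287 in library 6. That its cells were placed in other clusters was argued against: over the clusters with at least 100 cells in both libraries, the highest ratio of this rate to that of library 1 was 1.08 in these 3 libraries. Barcodes with at least 300 and under 1000 fragments had 0.754, 1.09 and 0.724 times the rate of the cells of libraries 4, 5 and 6. Hidden cells at the share of library 1, as deep as other shallow barcodes, would give at least 1.246 in library 4 and 1.021 in library 6. This assumes that they have the rate of cluster 7 cells with at least 1000 fragments. For library 4 that was the lowest rate measured, 21286 in library 2, and for library 6 that of its own 10 cells. The lower values seen argue against hidden cells of that share, depth and rate in these 2 libraries. Shallow cells may have a lower rate: in libraries 1 and 3, where cluster 7 was common, shallow barcodes had 0.74 and 0.736 times the rate of the cells. In library 5 such cells (621 among 8370 barcodes) need give no more than 0.46, so there the question stays open. A smaller share, a lower rate, shallower cells and cells under 300 fragments stay open in all 3 libraries. A loss of these cells before sequencing, and a difference between the fish, could both account for the pattern and stay open, as does genotype, which was not tested.

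The same cell barcode in a pair of libraries was seen 685 times, against 860.2 if barcodes were drawn evenly from the 565595 distinct ones in the file. A larger pool of possible barcodes would lower the number expected, and other pools were not examined.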
